A study of Homo sapiens with 12 samples.

How the data were processed

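RNA sequencing libraries of 2 human cell lines, each with lestaurtinib (500 nM, 24 h) or DMSO vehicle in 3 libraries, gave 4 groups and 12 libraries, grouped by the titles in the labels. Per the labels' protocols, total RNA was isolated with a miRNeasy kit and the libraries were TruSeq stranded mRNA libraries. Per the submitters' processing notes, STAR 2.7.3a and featureCounts 2.8.2 (the version as listed) were used with hg38. The strand setting of the counting is not given in the sources used here, so overlapping and antisense genes are uncertain. The authors' deposited table held whole-number read counts per gene, without normalization, and the authors' RPKM values, which follow from the same counts with 1 constant per library.

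The deposited table held 13869 genes, each with an RPKM above 1 in at least 1 library (the lowest maximum was 1.0005), and the listed counts were 99.71 to 99.77% of the reads that the RPKM values imply. Counts of genes under that level, and of mitochondrially encoded genes, were not analysed here. Totals ran from 32875940 to 55941446 counts per library. The common negative binomial dispersion gave a biological coefficient of variation of 0.125, and the median SD of log2 CPM over genes was 0.069 in treated MDAH-2774 and 0.113 to 0.119 in the other groups. Counts of replicate libraries differed beyond sampling noise in every pair (chi-square per degree of freedom 5.78 to 28.56), so no pair was treated as 1 library listed more than once.

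Counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, limma 3.58.1, R 4.3.3) in 1 fit of all 12 libraries with TMM scaling, 1 term per group and no block. The filterByExpr filter (minimum count 10) kept 13498 genes and removed 371. The contrasts were treated minus vehicle in each line and their difference, OVSAHO minus MDAH-2774, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01 on 34 of 36 lists with at least 5 genes, adjusted over the lists, and again with an estimated correlation and with fry. The untested lists were the markers of other cell types and the mitochondrially encoded genes. Some genes were members of several lists, so the lists are not independent of each other. The groups, tests, gene lists, the naming rule and the alternatives were fixed before the data were examined.

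Named genes were, per line, the 10 largest increases and decreases past the threshold with a mean of at least 5 CPM, no overlap between treated and vehicle libraries and a symbol that is not a clone, LINC, antisense, readthrough, pseudogene or small-RNA name. For both lines they were the 8 up and 8 down with the largest smaller change, and for the difference the 5 highest and 5 lowest with a mean of at least 5 CPM over all 12 libraries. Up to 4 members per list with at least 1 CPM and the lowest adjusted p were named, and JAK1, JAK2, FLT3, STAT3, SOCS3, BCL2L1, MYC, CYP1B1, CYP1A1, CDKN1A and MKI67 were reported in any case. Some genes that this rule names are not reported here. Genes named outside this rule were chosen after their values were seen.

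The tests were tried on 1 set of simulated counts with the real means, with 200 changed genes per line among 13498. In MDAH-2774 the DNA replication and S phase list was also raised 1.3-fold. In the MDAH-2774 comparison edgeR recovered 59% of genes changed 1.5-fold and 69% of genes changed 2-fold, and 10.6% of its calls were false. In OVSAHO it recovered 63% and 68%, and 7.1% of its calls were false. The false share in this set thus lay above the nominal 5% level, with 18 of 170 and 10 of 141 calls false. The simulation was not repeated, so the spread of this share is not known. The alternatives were other scaling (RLE, upper quartile), other filters, DESeq2 1.42.0, limma-voom, limma on log2(RPKM + 1) or log2(RPKM + 0.1), the replicate number as a block, each line alone and leaving out each library. GC content and length were taken from the GENCODE transcripts of the reference and matched by symbol. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.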

Results

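Gene expression was measured by RNA sequencing in 2 human ovarian cancer cell lines after 24 h with 500 nM lestaurtinib or with DMSO vehicle. MDAH-2774 is described by the submitters as an endometrioid ovarian cancer line, and OVSAHO is a line widely used as a model of high-grade serous ovarian cancer. Lestaurtinib is an indolocarbazole-type kinase inhibitor known to act on FLT3 and JAK2. Each of the 4 groups held 3 libraries, and the question put to the data was which genes the compound regulates. Total counts per library ran from 44016325 to 48408796 in treated and 36547466 to 44595957 in vehicle MDAH-2774 cells, and from 32875940 to 41768581 in treated and 40039225 to 55941446 in vehicle OVSAHO cells. Over the 500 genes with the highest variance across libraries, the first principal component held 96.9% of the variance and separated the lines. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Gene levels are CPM on TMM-scaled library sizes, given as mean ± SD with n = 3, fold changes are log2 values of lestaurtinib over vehicle with their SE, and coordinates are on hg38.

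In MDAH-2774, lestaurtinib lowered inflammatory, glycolytic, cell cycle and matrix genes and raised YAP-TEAD targets and FOXO-linked genes. CXCL8, the neutrophil chemokine interleukin 8 (chromosome 4, 73740506 to 73743716), fell from 169.6 ± 10.9 to 47.4 ± 2.21 CPM, a log2 change of -1.84 ± 0.17. HMOX1, the haem-degrading enzyme (chromosome 22, 35381067 to 35394214), fell from 147 ± 6.1 to 36.2 ± 2.39 CPM. FGFR2, a fibroblast growth factor receptor (chromosome 10, 121478330 to 121598656), rose from 17.1 ± 2.67 to 69.2 ± 3.42 CPM, and the vasodilator peptide gene ADM (chromosome 11, 10304980 to 10307402) rose from 97.5 ± 6.3 to 329 ± 23.0 CPM. Over all 13498 genes tested, 2312 passed an adjusted p of 0.05, of which 1090 were higher and 1222 lower. A log2 change of at least 1 in size was reached by 284 of them, 194 higher and 90 lower. With upper-quartile scaling the split was 1295 higher and 1014 lower, in limma on log2(RPKM + 1) 1533 and 1020, and the count fell to 1499 without treated replicate 1 and to 1463 without treated replicate 2.

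Among the genes with the largest increases in MDAH-2774, CDH5, the cadherin of endothelial junctions (chromosome 16, 66366622 to 66404786), went from 1.62 ± 0.304 to 12.9 ± 1.52 CPM. JDP2, a JUN-binding repressor (chromosome 14, 75427806 to 75472701), rose by 2.44 ± 0.13 on the log2 scale. ZBED2, GFRA1, MCF2L and RHOB rose by 1.96, 1.91, 1.68 and 1.62 on the same scale, and DHRS2 rose from 2.44 ± 1.54 to 9.74 ± 1.66 CPM. STK32B had a log2 change of 2.26 ± 0.64, but its call was lost without any 1 of 5 libraries (treated replicates 1, 2 and 3, vehicle replicates 1 and 2), with adjusted p from 0.061 to 0.1. The largest decreases were in NAV2 (chromosome 11, 19345247 to 20121601), from 27.5 ± 2.52 to 6.26 ± 0.915 CPM, and in HMOX1, CXCL8 and PLAUR, the urokinase receptor gene, which fell by 1.84 on the log2 scale. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, fell by 1.82, as did the hyaluronan synthase gene HAS3 and the AP-1 gene JUN. FOSL1 fell by 1.70. S100A3 had a log2 change of -1.81 ± 0.51 and lost its call without any 1 of 5 libraries (treated replicates 1, 2 and 3, vehicle replicates 2 and 3), with adjusted p from 0.05 to 0.11. In DESeq2 the calls of STK32B, GFRA1 and FOSL1 were lost (adjusted p = 0.39, 0.068 and 0.14), and in limma on log2(RPKM + 0.1) those of S100A3 and FOSL1 (adjusted p = 0.07 and 0.09).

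Of 26 measured NF-kB and inflammatory cytokine genes in MDAH-2774, 15 fell, 3 rose and 8 did not pass, and 17 fell and 3 rose when adjusted over the list alone. The list was lower as a whole (camera adjusted p = 3.5e-11, median log2 change -0.68), and examples were the mitochondrial superoxide dismutase gene SOD2 at -0.94, the NF-kB inhibitor gene NFKBIA at -0.72 and TNF at -1.03. Of 38 glycolysis and hypoxia genes, 28 fell, 3 rose and 7 did not pass, with the same counts of 28 and 3 adjusted over the list alone (list adjusted p = 3.8e-20, median -0.41). The glycolytic enzyme genes PKM and PGK1 fell by 0.78 and 0.80 on the log2 scale, while ADM rose. Among 21 ERK feedback and output genes, 8 fell and 3 rose, or 9 and 4 adjusted over the list alone (list adjusted p = 2.1e-05, median -0.50), with the transcription factor genes ETV4 and ETV5 at -1.35 and -1.29. Among 25 JAK-STAT target genes, 10 fell and 2 rose, or 11 and 3 adjusted over the list alone (list adjusted p = 0.00012, median -0.18). SOCS3, the feedback inhibitor of JAK signalling, was at -0.85 and BCL3 at -1.12. VEGFA, also a member of the glycolysis and hypoxia list, was at -0.63.

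Cell cycle lists were lower in MDAH-2774. Of 53 mitosis and G2-M genes, 28 fell and none rose over all genes, or 34 and 0 adjusted over the list alone (list adjusted p = 3.8e-14, median -0.27), with AURKB at -0.59, BUB1 at -0.49 and CCNB1 at -0.44. Of 54 DNA replication and S phase genes, 26 fell and 0 rose, or 36 and 1 adjusted over the list alone (list adjusted p = 8.1e-11, median -0.25), with the helicase subunit gene MCM7 at -0.33 and PCNA at -0.36. MKI67, which encodes the proliferation marker Ki-67, did not pass, at 263.5 ± 32.7 in vehicle and 249.6 ± 25.7 CPM in treated cells. Of 31 TGF-beta target and extracellular matrix genes, 13 fell and 4 rose, or 17 and 4 adjusted over the list alone (list adjusted p = 3.5e-10, median -0.34, or -0.59 without the 2 members that have too few counts for a fold). Fibronectin (FN1) fell by 1.10 and tenascin C (TNC) by 0.69, and thrombospondin 1 (THBS1) rose by 1.54. Of 15 mesenchymal genes, 5 fell and 0 rose, or 6 and 0 adjusted over the list alone (list adjusted p = 1.2e-06), with VIM at -0.52 and CDH2 at -0.62. Of 28 SRF and actin cytoskeleton genes, 12 fell and 2 rose, or 15 and 2 adjusted over the list alone (list adjusted p = 0.00018), with the tropomyosin genes TPM4 and TPM3 at -0.56 and -0.40. Of 22 NRF2 targets, 6 fell and 0 rose, or 7 and 0 adjusted over the list alone (list adjusted p = 2.3e-05), with HMOX1 at -2.02 and TXNRD1 at -0.53. Of 39 lysosome and autophagy genes, 8 fell and 3 rose, or 10 and 4 adjusted over the list alone (list adjusted p = 0.017), with SQSTM1 at -0.37 and CTSB at -0.31.

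Higher lists in MDAH-2774 included YAP-TEAD targets, of which 12 of 24 rose and 1 fell, or 13 and 1 adjusted over the list alone (list adjusted p = 1.1e-09, median 0.29). The transcription factor gene TEAD1 rose by 0.78, AJUBA by 0.70 and the matricellular gene CCN1 by 1.16. Of 25 FOXO target and PI3K feedback genes, 6 rose and 0 fell, or 11 and 0 adjusted over the list alone (list adjusted p = 0.00047, median 0.31), with the insulin receptor substrate gene IRS2 at 1.04, CITED2 at 1.06 and TRIB2 at 1.58. Of 26 cholesterol synthesis genes, 7 rose and 0 fell, or 8 and 0 adjusted over the list alone (list adjusted p = 0.0045), with CYP51A1 at 0.38. These 14 lists were called also with an estimated correlation between genes, out of 21 lists called of 34 tested, 6 higher and 15 lower.

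The other 7 calls in MDAH-2774 were lost with an estimated correlation. JAK-STAT pathway components (8 of 33 fell, 2 rose; 10 and 2 adjusted over the list alone) had an adjusted p of 0.03, and adjusted p = 0.15 with an estimated correlation, with OSMR at -0.55 and IL4R at -0.51. Immediate early AP-1 genes (8 of 20 fell, 4 rose; 10 and 5 adjusted over the list alone) had 0.035, and adjusted p = 0.42 with an estimated correlation, with JUN at -1.82 and NR4A1 at 1.39. Homologous recombination and DNA repair genes (9 of 44 fell, 2 rose; 9 and 2 adjusted over the list alone) had 0.035, and adjusted p = 0.24 with an estimated correlation, with PARP1 at -0.23 and ATM at 0.56. Lestaurtinib-bound kinases (3 of 14 fell, 0 rose; 3 and 0 adjusted over the list alone) had 0.035, and adjusted p = 0.083 with an estimated correlation, with AURKB at -0.59 and JAK1 at -0.22. Replication-dependent histone genes (3 of 19 rose, 0 fell; 4 and 0 adjusted over the list alone) had 0.012, and adjusted p = 0.075 with an estimated correlation, with H2BC12 at 0.96. Fatty acid synthesis genes (3 of 17 rose, 0 fell; 3 and 0 adjusted over the list alone) had 0.04, and adjusted p = 0.084 with an estimated correlation, with the desaturase gene SCD at 0.41. Cytosolic ribosomal protein genes (8 of 61 rose, 0 fell; 7 and 0 adjusted over the list alone) had 0.03, and adjusted p = 0.64 with an estimated correlation, with RPL22 at 0.32.

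Calls of 6 of these lists were also lost when 1 library was left out. The adjusted p of the DNA repair list was 0.056 without treated replicate 2 and 0.082 without vehicle replicate 1. For the AP-1 list it was 0.055 without treated replicate 3 and 0.093 without vehicle replicate 3. The fatty acid list had 0.054 without treated replicate 3 and 0.12 without vehicle replicate 1. The kinase list had 0.054, 0.071 and 0.093 without treated replicate 3, vehicle replicate 1 and vehicle replicate 3. The ribosomal protein list had 0.15, 0.18 and 0.13 without treated replicate 3, vehicle replicate 2 and vehicle replicate 3, and the JAK-STAT component list 0.079 without vehicle replicate 2. The fatty acid and ribosomal protein calls were also lost with median-ratio scaling (adjusted p = 0.06 and 0.068), the kinase call in limma on log2(RPKM + 1) (0.052) and the AP-1 call in limma on log2(RPKM + 0.1) (0.051).

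Camera made no call in MDAH-2774 for 13 lists. Of these, fry called the antigen presentation (fry adjusted p = 0.014), heat shock (0.007) and lineage (0.024) lists. Members that rose and fell were 0 and 2 of 44 interferon-stimulated genes, 1 and 2 of 19 antigen presentation genes, 2 and 2 of 11 aryl hydrocarbon receptor targets, 2 and 5 of 28 p53 target genes, and 2 and 4 of 28 BCL2 family and apoptosis genes. They were 7 and 4 of 36 integrated stress response genes, 2 and 1 of 24 endoplasmic reticulum chaperones, 2 and 7 of 19 heat shock genes, 6 and 7 of 29 epithelial junction and keratin genes, and 0 and 3 of 20 ovarian and mullerian lineage markers. They were 2 and 1 of 19 drug efflux and platinum response genes, 2 and 1 of 38 MYC target and ribosome biogenesis genes, and 3 and 1 of 42 nuclear respiratory chain genes. When adjusted over the list alone the counts were 3 and 5 for p53 targets, 7 and 5 for the integrated stress response, 4 and 7 for heat shock, 7 and 7 for epithelial genes, 1 and 0 for MYC targets and 2 and 1 for the respiratory chain, and the same as over all genes for the others. Median, mean and test differed in sign for the antigen presentation, p53, heat shock, lineage, drug efflux and respiratory chain lists, with the median of the last 3 at 0. The lineage median was -0.1 without the 5 members that have too few counts for a fold and with bounds in place of fitted values where 1 group was at 0. The pro-apoptotic BMF fell by 1.47 and the anti-apoptotic BCL2L1 rose by 0.35, and PAX8, a mullerian lineage factor, fell by 0.73. Of the markers of fibroblasts, blood cells and endothelium, 4 were measured. CDH5 rose and CD68 fell from 26.3 ± 2.6 to 9.55 ± 0.858 CPM, while COL1A1 (4.41 ± 1.24 and 6.05 ± 0.314 CPM) and ACTA2 (1.13 ± 0.487 and 1.71 ± 0.446 CPM) did not pass.

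In OVSAHO, lestaurtinib raised inflammatory, chaperone, cholesterol synthesis and cytoskeletal genes and lowered interferon-stimulated genes and lineage markers. The imprinted, retrotransposon-derived PEG10 (chromosome 7, 94656325 to 94669695) rose from 534 ± 9.13 to 3676 ± 82.6 CPM, a log2 change of 2.78 ± 0.05. CGA, the shared alpha subunit of glycoprotein hormones (chromosome 6, 87085498 to 87095147), rose from 0.671 ± 0.34 to 17.1 ± 1.71 CPM, and the somatostatin gene SST (chromosome 3, 187668906 to 187670413) from 43.2 ± 2.05 to 230.4 ± 30.6 CPM. DLGAP3, a synaptic scaffold gene (chromosome 1, 34862120 to 34929585), fell from 229.6 ± 18.3 to 58.9 ± 4.89 CPM. In OVSAHO 2124 genes passed, 1241 higher and 883 lower, and 332 had a log2 change of at least 1 in size, 181 higher and 151 lower. With upper-quartile scaling the split was 999 higher and 1173 lower, and in limma on log2(RPKM + 1) 1037 higher and 1062 lower.

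The genes with the largest increases in OVSAHO also included TESC at 3.03, TCIM at 2.90, SLC14A2 at 2.56, the phosphatase gene DUSP1 at 2.50 (chromosome 5, 172768090 to 172771200), MPZL2 at 2.42, HPD at 2.28 and SRGN at 2.25. The largest decreases were in the anion transporter gene SLC26A7 at -2.51 (chromosome 8, 91209494 to 91398155), CRISPLD2 at -2.36, the retinaldehyde dehydrogenase gene ALDH1A1 at -2.16, the glutamate receptor genes GRIN2A and GRIK2 at -2.12 and -2.08, and TNFSF10, which encodes the death ligand TRAIL, at -2.05. CTNNA2 and BBOX1 had log2 changes of -2.02 and -2.01, and GALNT3 fell from 61.5 ± 5.38 to 15.4 ± 0.561 CPM. The call of CTNNA2 was lost in DESeq2 (adjusted p = 0.12).

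Of 26 NF-kB and inflammatory cytokine genes in OVSAHO, 17 rose, 0 fell and 9 did not pass, or 18 and 0 adjusted over the list alone (camera adjusted p = 1.8e-15, median 0.75). The cytokine gene LIF rose by 0.97, NFKB2 by 0.89 and CXCL8, at low counts, from 1.26 ± 0.688 to 3.41 ± 0.722 CPM. Of 26 cholesterol synthesis genes, 17 rose and 0 fell, or 19 and 0 adjusted over the list alone (list adjusted p = 2e-14, median 0.40, or 0.46 over the members with a count), with DHCR7 at 0.63, FDFT1 at 0.55 and the mevalonate kinase gene MVK at 1.06. Of 24 endoplasmic reticulum chaperones, 15 rose and 0 fell, or 21 and 0 adjusted over the list alone (list adjusted p = 9.5e-13, median 0.35), with HSPA5 at 0.52 and PDIA4 at 0.48. Of 24 YAP-TEAD targets, 11 rose and 2 fell, or 13 and 2 adjusted over the list alone (list adjusted p = 2.3e-05, median 0.23), with CCN2 at 1.68, CRIM1 at 0.81 and MYOF at -0.65. Of 28 SRF and actin cytoskeleton genes, 13 rose and 4 fell, or 16 and 4 adjusted over the list alone (list adjusted p = 3.2e-06, median 0.21), with CALD1 at 1.18, TAGLN at 1.34 and ACTB at 0.48. Of 44 interferon-stimulated genes, 17 fell and 2 rose, or 20 and 2 adjusted over the list alone (list adjusted p = 3e-06, median -0.36), with the antiviral gene MX1 at -1.19, IFITM1 at -0.70 and ISG20 at 2.05. Of 20 ovarian and mullerian lineage markers, 9 fell and 2 rose, or 9 and 2 adjusted over the list alone (list adjusted p = 2e-04, median -0.29), with the kallikrein genes KLK7 and KLK6 at -1.14 and -0.66 and WT1 at -0.53. These 7 lists, out of 15 called (12 higher and 3 lower), were called also with an estimated correlation.

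The other 8 calls in OVSAHO were lost with an estimated correlation. Of 21 ERK feedback and output genes, 9 rose and 2 fell, or 10 and 2 adjusted over the list alone. PHLDA1 was at 1.78 and SPRY2, which rose in MDAH-2774 too, at 1.29. ETV4 and ETV5, lower in MDAH-2774, were lower in OVSAHO too, at -0.58 and -0.47. The list had a camera adjusted p of 0.00072, and adjusted p = 0.051 with an estimated correlation. Immediate early AP-1 genes (9 of 20 rose, 0 fell; 12 and 1 adjusted over the list alone) had 9.3e-08, and adjusted p = 0.071 with an estimated correlation, with DUSP1 at 2.50 and IER3 at 1.44. TGF-beta target and matrix genes (7 of 31 rose, 4 fell; 9 and 5 adjusted over the list alone) had 0.0078, and adjusted p = 0.064 with an estimated correlation, and their median of 0.04 and mean of -0.02 differed in sign, with LAMA3 at 1.20 and FN1 at -1.16. This call was also lost in limma-voom (adjusted p = 0.28) and in limma on RPKM values (0.32 and 0.36), and that of FN1 in limma-voom (0.099) and limma on log2(RPKM + 1) (0.067). Glycolysis and hypoxia genes (11 of 38 rose, 1 fell; 13 and 2 adjusted over the list alone) had 0.003, and adjusted p = 0.14 with an estimated correlation, with LDHA at 0.43. Mitosis and G2-M genes (13 of 53 rose, 1 fell; 17 and 2 adjusted over the list alone) had 0.013, and adjusted p = 0.43 with an estimated correlation, with ECT2 at 0.65 and CDC20 at 0.39. MYC targets and ribosome biogenesis genes (11 of 38 rose, 2 fell; 13 and 2 adjusted over the list alone) had 0.017, and adjusted p = 0.25 with an estimated correlation, with TFRC at 0.43. Heat shock genes (5 of 19 rose, 0 fell; 8 and 0 adjusted over the list alone) had 0.048, and adjusted p = 0.14 with an estimated correlation. HSPA1A and HSPA1B among them are near-identical copies whose counts are uncertain, and their calls were lost without treated replicate 3 (adjusted p = 0.095 and 0.12) or vehicle replicate 2 (0.077 and 0.091). Cytosolic ribosomal protein genes (10 of 61 fell, 4 rose; 13 and 4 adjusted over the list alone) had 0.049, and adjusted p = 0.67 with an estimated correlation, with RPL12 at -0.19.

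Calls of 4 of these lists in OVSAHO were lost when 1 library was left out. The mitosis list had an adjusted p of 0.11 without treated replicate 1 and 0.13 without vehicle replicate 1. The heat shock list had 0.1, 0.055 and 0.056 without treated replicates 1, 2 and 3, and 0.094 and 0.078 without vehicle replicates 1 and 3. The MYC list had 0.054, 0.055 and 0.11 without treated replicate 1, treated replicate 3 and vehicle replicate 1. The ribosomal protein list had 0.14 without treated replicate 2 and 0.13 without vehicle replicate 2. The heat shock call was also lost with median-ratio scaling (adjusted p = 0.056), upper-quartile scaling (0.09) and either other filter (0.057 and 0.053), the MYC call with upper-quartile scaling (0.063), and the ribosomal protein call with the strict filter (0.053).

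Camera made no call in OVSAHO for 19 lists. Of these, fry called the lysosome (fry adjusted p = 4.7e-05), FOXO (0.00014), fatty acid (0.0046) and drug efflux (0.0046) lists. It also called the NRF2 (0.008), kinase (0.021), aryl hydrocarbon receptor (0.032) and epithelial (0.032) lists. Members that rose and fell were 4 and 4 of 25 JAK-STAT target genes, 5 and 4 of 33 JAK-STAT pathway components, 4 and 5 of 19 antigen presentation genes, 2 and 1 of 11 aryl hydrocarbon receptor targets, and 3 and 6 of 54 DNA replication and S phase genes. They were 1 and 0 of 19 replication-dependent histone genes, 3 and 7 of 44 homologous recombination and DNA repair genes, 3 and 5 of 28 p53 target genes, 4 and 2 of 28 BCL2 family and apoptosis genes, and 2 and 5 of 36 integrated stress response genes. They were 4 and 4 of 17 fatty acid synthesis genes, 6 and 1 of 39 lysosome and autophagy genes, 2 and 7 of 25 FOXO target and PI3K feedback genes, 3 and 4 of 15 mesenchymal genes, and 5 and 4 of 29 epithelial junction and keratin genes. They were 2 and 0 of 14 lestaurtinib-bound kinases, 2 and 4 of 19 drug efflux and platinum response genes, 2 and 5 of 22 NRF2 targets, and 2 and 1 of 42 nuclear respiratory chain genes. When adjusted over the list alone the counts were 5 and 4 for JAK-STAT targets, 6 and 7 for JAK-STAT components, 5 and 6 for antigen presentation, 3 and 1 for aryl hydrocarbon receptor targets, 0 and 0 for histones, 4 and 5 for p53 targets and 4 and 3 for apoptosis genes. They were 7 and 1 for lysosome genes, 2 and 8 for FOXO targets, 5 and 5 for mesenchymal genes, 5 and 5 for epithelial genes and 2 and 6 for drug efflux genes, and the same as over all genes for the others. Median, mean and test differed in sign for the JAK-STAT component, DNA replication, p53, FOXO, mesenchymal, epithelial and respiratory chain lists. KRT18 and KRT8 rose by 1.08 and 0.70, TAP1 rose by 1.06, TXNIP fell by 0.85 and VIM fell by 0.61. The mitochondrially encoded genes were not analysed here. CDH5 and CD68 moved in the same direction in OVSAHO as in MDAH-2774. CDH5 went from 0.13 ± 0.166 to 1.56 ± 0.391 CPM and CD68 from 14.7 ± 0.535 to 10.6 ± 1.86 CPM. The log2 change of CD68 was smaller in OVSAHO, at -0.46 against -1.46 (test of the difference, adjusted p = 0.00307).

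**Figure D1:**
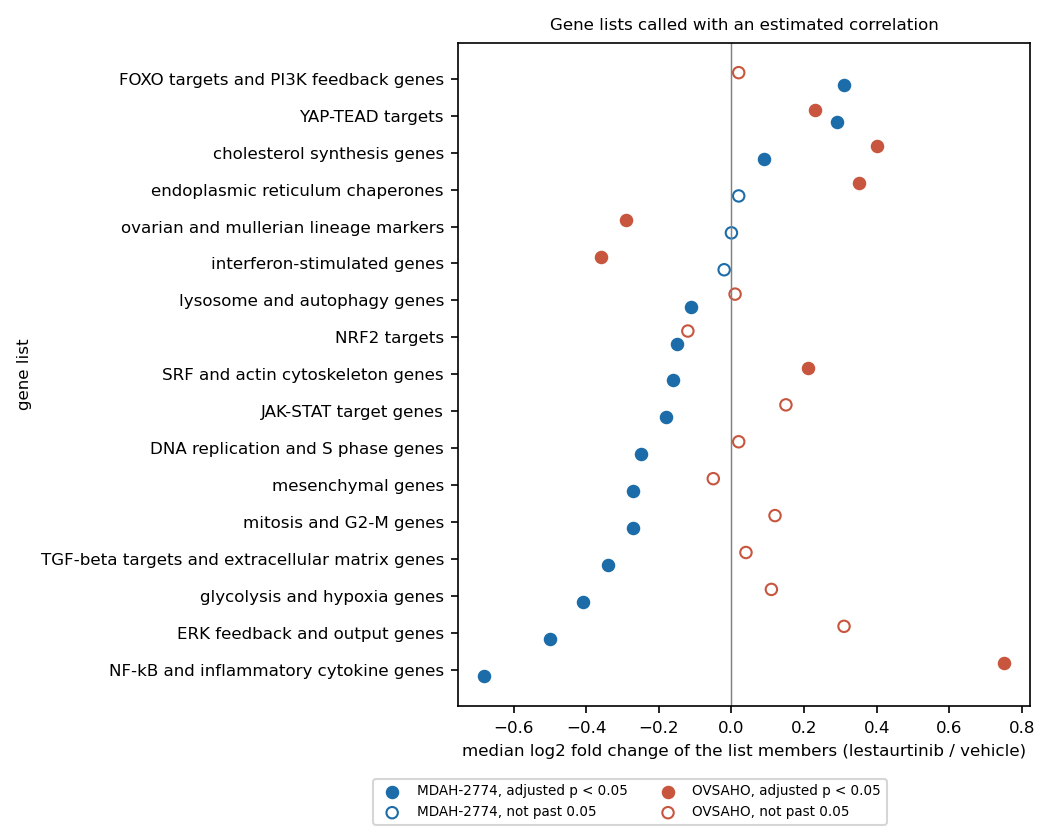
Median log2 fold change of the members of each gene list in MDAH-2774 (blue) and OVSAHO (red), for the lists called in at least 1 line by camera with an estimated correlation. Filled points passed an adjusted p of 0.05 in that line. The inflammatory cytokine list lies at -0.68 in MDAH-2774 and 0.75 in OVSAHO.

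Some genes changed in the same direction in both lines. ZBED2, a zinc finger gene (chromosome 3, 111592900 to 111595335), rose by 1.96 ± 0.15 in MDAH-2774 and 1.79 ± 0.15 in OVSAHO, and RHOB, a small GTPase gene (chromosome 2, 20447071 to 20449445), by 1.62 ± 0.16 and 2.17 ± 0.15. BMF (chromosome 15, 40087890 to 40108884) fell by 1.47 in each line, from 19.3 ± 2.6 to 6.98 ± 0.993 CPM and from 14.2 ± 1.28 to 5.11 ± 1.41 CPM. In the same direction changed 352 genes, 190 higher and 162 lower, against 100.2 and 79.9 for independent lists (Fisher's exact test, two-sided, p = 3.6e-19 and 3e-19, with genes that are not independent replicates). In opposite directions changed 256 genes. Of these, 172 were lower in MDAH-2774 and higher in OVSAHO against 112.4 for independent lists (Fisher's exact test, p = 5e-09), and 84 went the other way against 71.3 (Fisher's exact test, p = 0.11). Across genes, which are not independent replicates, the log2 changes of the lines had a Pearson r of 0.0095 and a Spearman rho of 0.0174.

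Other genes higher in both lines were NR4A1 (1.39 and 1.33), the ERK pathway inhibitor SPRY2 (1.26 and 1.29), the YAP-TEAD target CCN2 (1.02 and 1.68), AFF1 (1.02 and 0.96), the cyclic AMP phosphodiesterase gene PDE4D (0.95 and 1.57) and JDP2 (2.44 and 0.91), with MDAH-2774 first. Lower in both were the epithelial transcription factor gene ELF3 (-1.06 and -0.98), the cholesterol exporter gene ABCA1 (-0.92 and -1.20), FGFRL1 (-0.88 and -0.89), DUSP10 (-0.84 and -1.65), CRABP2 (-1.27 and -0.82) and HOMER2 (-0.93 and -0.82). The YAP-TEAD and cholesterol synthesis lists were higher in both lines.

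**Figure D2:**
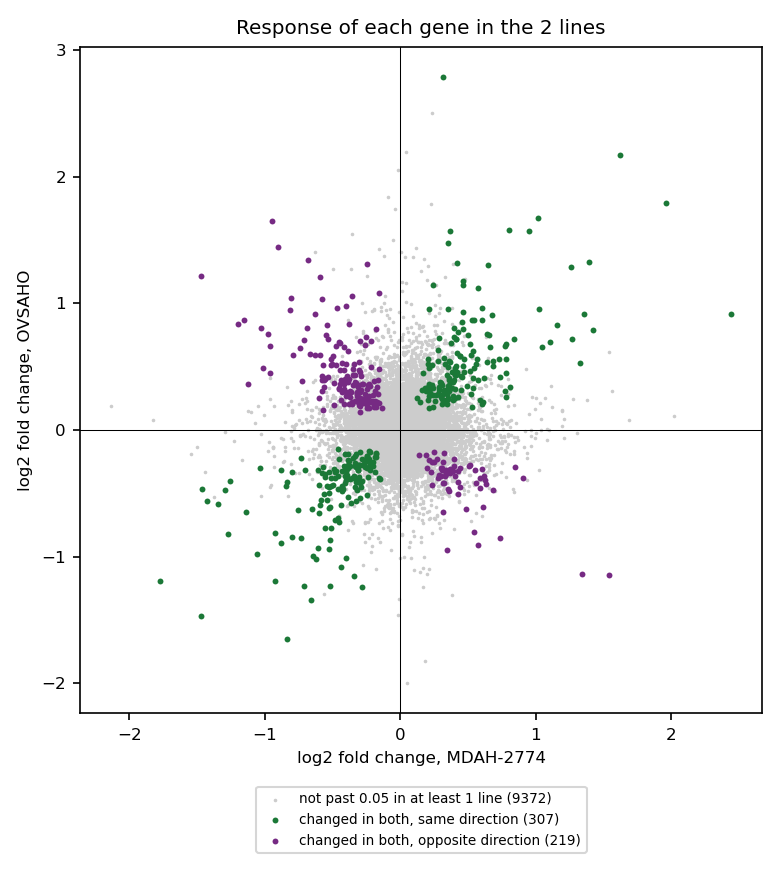
Log2 fold change in MDAH-2774 (x axis) against OVSAHO (y axis) for the 9898 genes with a mean of at least 5 CPM in each line. Green points are the 307 genes that passed in both lines in the same direction, purple points the 219 that passed in opposite directions, and grey points the 9372 others.

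The genes and pathways that the compound is known for were read out whether changed or not. JAK1 fell in MDAH-2774 from 388 ± 13.5 to 333 ± 2.97 CPM and was at 143 ± 1.05 and 132 ± 2.31 CPM in OVSAHO, where it did not pass (adjusted p = 0.0916) but passed with upper-quartile scaling, in DESeq2 and in limma on RPKM values. JAK2 did not pass in either line, at 4.62 ± 2.2 and 5.93 ± 0.352 CPM in MDAH-2774 and 4.71 ± 0.741 and 3.33 ± 0.786 CPM in OVSAHO. STAT3 fell in OVSAHO by 0.38 ± 0.05, and in MDAH-2774 by 0.16 ± 0.05, where the call was lost with upper-quartile scaling, in limma on RPKM values and without any 1 of 4 libraries (treated replicates 1 and 2, vehicle replicates 1 and 2; adjusted p from 0.061 to 0.17). SOCS3 fell from 69.0 ± 9.81 to 38.3 ± 1.56 CPM in MDAH-2774 and was at 38.8 ± 4.75 and 35.3 ± 2.79 CPM in OVSAHO, where it did not pass. BCL2L1 rose by 0.35 and 0.25 and MYC by 0.39 and 0.26 in MDAH-2774 and OVSAHO. The OVSAHO call of BCL2L1 was lost without vehicle replicate 3 (adjusted p = 0.063), and that of MYC in limma on RPKM values and without any 1 of 5 libraries (treated replicates 2 and 3, vehicle replicates 1, 2 and 3; adjusted p from 0.057 to 0.16). CYP1B1, a target of the aryl hydrocarbon receptor, rose in OVSAHO by 0.76 ± 0.16 and did not pass in MDAH-2774. CDKN1A fell in both lines, in OVSAHO from 3.48 ± 1.35 to 1.02 ± 0.534 CPM. MKI67 was at 521 ± 6.4 and 491 ± 19.2 CPM in OVSAHO and did not pass. FLT3 and CYP1A1 were not analysed here.

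The test of the difference between the lines, taken as the response of OVSAHO minus that of MDAH-2774, called 2268 genes, 1244 higher and 1024 lower. With upper-quartile scaling the split was 898 higher and 1376 lower, and in limma on log2(RPKM + 1) 1023 and 1547. The 10 genes with the largest differences included several that were near or at 0 in 1 line, so that their fitted folds depend on the settings of the fit, and their counts are given here. In MDAH-2774, LRRN2, IGFBP5, PDE6B and CAPN9 had no count in the 3 vehicle libraries and 57, 51, 58 and 28 counts summed over the treated libraries. In OVSAHO, LHFPL6, TGFA, TMEM92 and C6orf141 had no count in vehicle and 28, 21, 21 and 9 counts in treated libraries. All 21 counts of TGFA and of TMEM92 came from treated replicate 1, and all 9 of C6orf141 from treated replicate 2. Without that library the log2 difference was 0.19, 0.80 and 0.75 and did not pass. TGFA was also lost without any other library but treated replicates 2 and 3 of OVSAHO (adjusted p from 0.054), C6orf141 without any other but treated replicates 1 and 3 of OVSAHO (from 0.057), and TMEM92 without vehicle replicate 1 (0.054) or 3 (0.051) of OVSAHO. In limma-voom and limma on log2(RPKM + 0.1), TMEM92 (adjusted p = 0.26 and 0.12), TGFA (0.38 and 0.38) and C6orf141 (0.32 and 0.073) were lost. TMEM92 and TGFA were lost in DESeq2 (adjusted p = 0.054 and 0.088), and CAPN9 in limma-voom (0.13). Limma on log2(RPKM + 1) lost LHFPL6 and TGFA (adjusted p = 0.17 and 0.28). KBTBD11 had 12, 0 and 24 counts in treated and 1, 0 and 0 in vehicle OVSAHO libraries, and KCNMA1, a potassium channel gene, had 0 in each treated and 7, 28 and 14 in vehicle OVSAHO libraries. The KBTBD11 call was lost in limma-voom (adjusted p = 0.23) and in limma on log2(RPKM + 0.1) (0.73). With log2(RPKM + 1) the KBTBD11 difference reversed and did not pass (0.51). The KCNMA1 difference reversed in limma on RPKM values and passed with log2(RPKM + 1) (0.41, adjusted p = 0.01).

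Genes with a mean of at least 5 CPM in each line were chosen after the values were seen. The crosslinking enzyme gene TGM2 (chromosome 20, 38128461 to 38166509) fell from 1148 ± 25.9 to 594 ± 13.2 CPM in MDAH-2774 and rose from 622 ± 40.2 to 1956 ± 51.1 CPM in OVSAHO, a difference of 2.60 ± 0.07. IER3 also fell in MDAH-2774 (-0.91) and rose in OVSAHO (1.44). THBS1 rose in MDAH-2774 from 24.4 ± 4.09 to 71.0 ± 7.42 CPM and fell in OVSAHO from 17.1 ± 0.304 to 7.78 ± 2.02 CPM, and SORL1 rose by 1.34 and fell by 1.14. FGFR2 had a difference of -1.91 ± 0.12, with 153 ± 5.19 and 165 ± 7.14 CPM in OVSAHO. PEG10 had a difference of 2.47 ± 0.07.

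Of 34 lists, 18 differed between the lines, 15 higher and 3 lower in OVSAHO relative to MDAH-2774, and 14 of them also with an estimated correlation. The inflammatory cytokine list had the largest median difference of these 18, at 1.11 (camera adjusted p = 5.2e-28), with 19 of 26 members higher and 0 lower, or 21 and 0 adjusted over the list alone. Immediate early AP-1 genes followed at 0.59 (9 of 20 higher, 0 lower; 10 and 0 adjusted over the list alone), then glycolysis and hypoxia genes at 0.56 (27 of 38 higher, 1 lower; 29 and 1 adjusted over the list alone), SRF and actin genes (0.39; 16 of 28 and 1; 19 and 2 adjusted over the list alone) and mitosis genes (0.37; 33 of 53 and 0; 35 and 0 adjusted over the list alone). Interferon-stimulated genes were lower by a median of -0.28 (9 of 44 lower, 1 higher; 13 and 1 adjusted over the list alone) and FOXO targets by -0.42 (8 of 25 lower, 0 higher; 9 and 1 adjusted over the list alone). The calls of JAK-STAT target genes (adjusted p = 0.071 with an estimated correlation), mesenchymal genes (adjusted p = 0.14 with an estimated correlation), lestaurtinib-bound kinases (adjusted p = 0.083 with an estimated correlation) and ribosomal proteins (adjusted p = 0.47 with an estimated correlation) were lost. The kinase call was also lost without vehicle replicate 1 (0.072) or vehicle replicate 3 (0.076) of MDAH-2774, and the mesenchymal call without vehicle replicate 1 of OVSAHO (0.051). The mesenchymal call was lost in limma-voom (0.28) and in limma on RPKM values (0.14 and 0.19), and the kinase call with upper-quartile scaling (0.06) and in limma-voom (0.057). Of the 16 lists not called by camera, fry called the JAK-STAT component (fry adjusted p = 0.0018), NRF2 (0.0065), MYC (0.012) and YAP-TEAD (0.041) lists. Among the 16, median, mean and test differed in sign for the antigen presentation, YAP-TEAD, p53, apoptosis, fatty acid and respiratory chain lists.

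**Figure D3:**
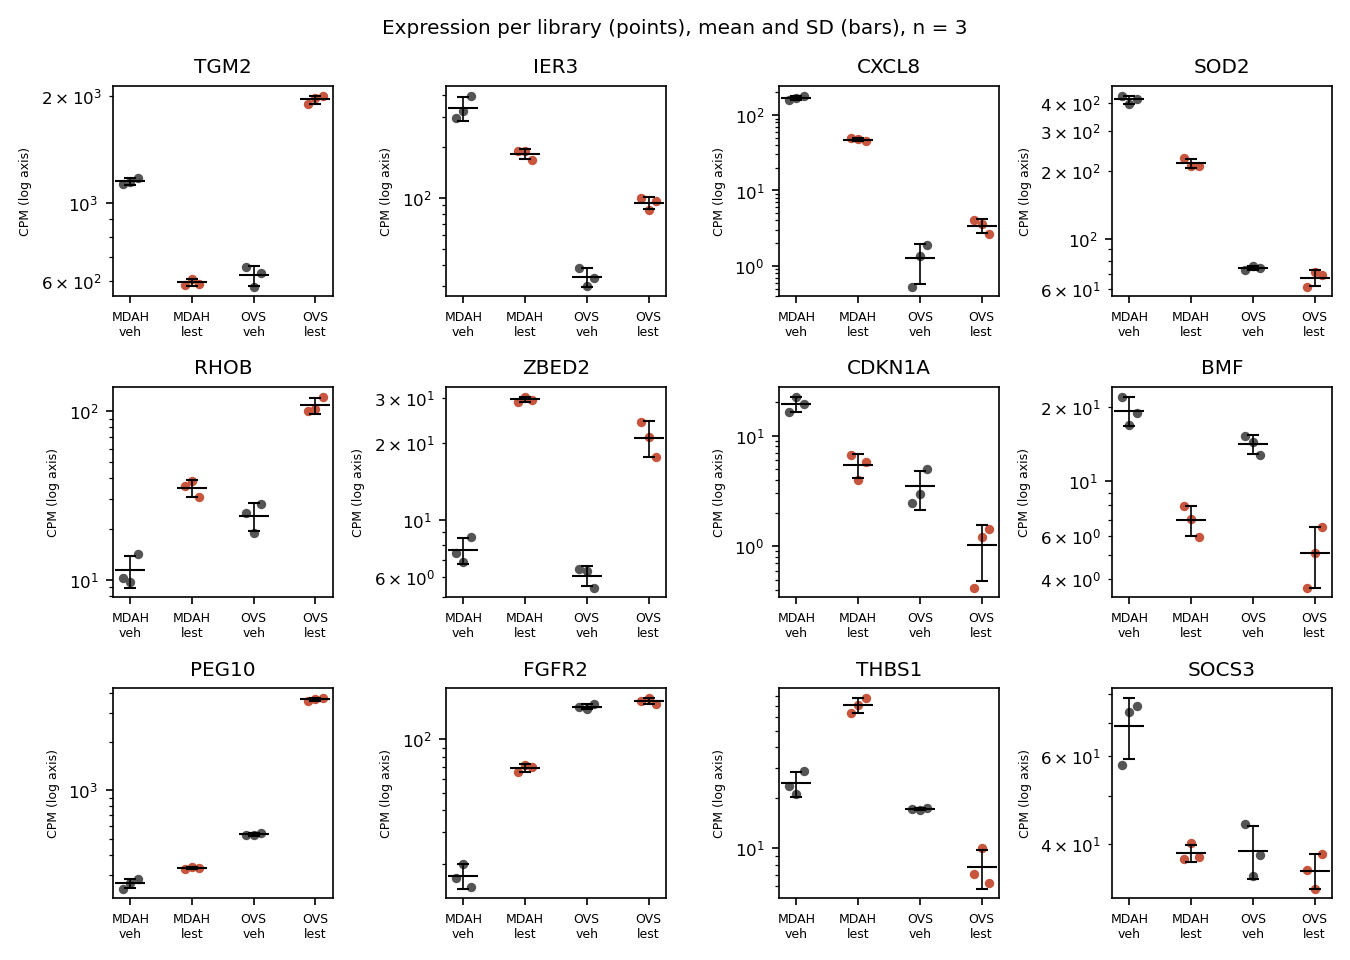
Expression per library of 12 genes, with CPM on a log axis. Points are libraries, bars the mean and SD of 3, grey vehicle and red lestaurtinib; the genes were chosen after the values were seen. TGM2 falls from 1148 to 594 CPM in MDAH-2774 and rises from 622 to 1956 CPM in OVSAHO.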

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

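The test for reads of the other cell line and the comparisons of total depth between vehicle and treated libraries were chosen only after the results were seen, and the other tests were set before theirs. The lines differed in their response by the test of the difference itself in 2268 genes and 18 lists. The libraries were split within both lines in 100 ways, drawn at random with the real one included. Of these, 1 gave as many genes (2268, highest other 629) and 1 as many lists (18, highest other 16). Every other drawn split scrambled at least 1 line, so the splits cannot decide whether 2 real responses differ. Those with the real groups kept in 1 line gave 206 to 629 genes and 8 to 16 lists. The split with the treatment reversed in 1 line was not among those drawn. For genes changed in the same direction, 1 of the 100 splits gave as many (352, highest other 3). A scrambled line alone called at most 8 genes, so the shared count of the other splits was low beforehand. That test cannot decide whether the overlap of 2 real responses is chance. For the correlation 69 of the 100 gave an r as far from 0 in either direction as the real 0.01 (highest other 0.038), so chance is not excluded for it. Within a line there are 10 splits, too few for a share under 0.05. In MDAH-2774 the real split gave 2312 genes and 21 lists and the highest other 2 genes and 10 lists, and in OVSAHO 2124 genes and 15 lists against 8 and 8. The scrambled splits called 5 to 10 lists in MDAH-2774 and 1 to 8 in OVSAHO with almost no genes, so a list call at the preset correlation alone is weak evidence.

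The lists that differed had these median differences of log2 change, OVSAHO minus MDAH-2774. Higher were NF-kB and inflammatory cytokine genes 1.11, immediate early AP-1 genes 0.59, glycolysis and hypoxia genes 0.56, SRF and actin genes 0.39, mitosis and G2-M genes 0.37, JAK-STAT target genes 0.34, TGF-beta targets 0.34 (0.44 without the 2 members that have too few counts for a fold), endoplasmic reticulum chaperones 0.31, ERK feedback genes 0.25, cholesterol synthesis genes 0.25, DNA replication genes 0.23, heat shock genes 0.21, lysosome genes 0.17, mesenchymal genes 0.17 and lestaurtinib-bound kinases 0.15. Lower were FOXO targets -0.42, interferon-stimulated genes -0.28 and ribosomal proteins -0.12. Of the always reported genes, STAT3 differed by -0.22 and SOCS3 by 0.71. Of the genes at 5 CPM or more in each line, chosen after the values were seen, TGM2 differed by 2.6, PEG10 by 2.47, IER3 by 2.35, NAV2 by 2.32, DUSP1 by 2.27, DAAM2 by 2.15 and ISG20 by 2.07. THBS1 differed by -2.68, SORL1 by -2.47, GALNT3 by -2.05, YPEL2 by -2.01, FGFR2 by -1.91, CHRDL1 by -1.68, MCF2L by -1.61 and PLXDC2 by -1.59. Fitted values that depend on counts near 0 were 7.01 for TMEM92, 6.86 for LHFPL6, 6.38 for TGFA, 5.74 for C6orf141, 4.87 for KBTBD11, -7.91 for LRRN2, -7.67 for IGFBP5, -7.38 for PDE6B, -6.98 for CAPN9 and -6.48 for KCNMA1. Of the 60 genes named for a line or both lines, or always reported, 24 passed the test of the difference. It could not decide for CGA, SST, ALDH1A1, GRIN2A, TNFSF10 and BBOX1, which had no count in any MDAH-2774 library. The test could say little about TCIM, MPZL2, SLC14A2 and SRGN, which had 7, 5, 1 and 1 counts in MDAH-2774, each in 1 library.

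The inflammatory list was lower in MDAH-2774 and higher in OVSAHO. Library depth was argued against: with all libraries thinned to the lowest total the median difference was 1.1 (1.11 before), with a camera adjusted p of 1.8e-29 and 7.6e-05 with an estimated correlation. Gene length and GC content were argued against as the whole cause, since removing their trend left 1.05, with values for 26 of 26 members, although log2 change followed GC in OVSAHO (rho 0.235 across genes). The other lists called in OVSAHO or for the difference were not corrected for this trend. A biological difference between the lines, which the design names, remains open and untested.

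The genes without a count in vehicle and counted in treated libraries of 1 line were weighed against reads of the other line, where their levels were higher. Transcripts with at least 20 CPM there and no count in this line's vehicle libraries stood at a median of 0% of the other line's level in treated MDAH-2774 (35 genes, 21 at 0) and 0% in treated OVSAHO (19 genes, 14 at 0). The named genes stood at medians of 2.56% and 2.06%, which argues against such reads as the source of all of them. The vehicle total was 0.875 times the treated total in MDAH-2774 and 1.29 times in OVSAHO. The latter argues against a lower depth of the vehicle libraries in OVSAHO. In MDAH-2774 depth alone would give each of the 4 genes at least 24.5 vehicle counts against the 0 counted. These genes were picked at 0 in vehicle from calls already scaled for depth, so this comparison decides nothing further. Thinning, planned for this, likewise decides nothing for genes picked at 0. TGFA, TMEM92 and C6orf141 rest on 1 library each.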

How the results depend on the processing

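No alternative here was chosen after the results were seen. Of the genes called, 1173 of 2312 in MDAH-2774, 1025 of 2124 in OVSAHO and 1216 of 2268 for the difference were called in the same direction in every alternative counted, which leaves out the fits of 1 line alone, the required log2 change and, within a line, the omission of libraries of the other line. Requiring a log2 change of at least 1 left 284 and 332 genes by construction. Leaving out 1 library gave 1463 to 2098 genes in MDAH-2774, 1460 to 2184 in OVSAHO, 1622 to 2322 for the difference, 241 to 363 in the same direction in both lines and an r from -0.012 to 0.021. It gave 17 to 21 lists in MDAH-2774, 12 to 14 in OVSAHO and 17 to 19 for the difference. Fewer samples enter these fits. The correlation was 0.075 with log2(RPKM + 1) and 0.05 with log2(RPKM + 0.1), and the cause was not tested. An estimated correlation left 14 lists in MDAH-2774, 7 in OVSAHO and 14 for the difference. Fry called 22, 22 and 21 lists, of which 19, 14 and 17 were camera calls in the same direction. With fry the AP-1 (fry adjusted p = 0.052) and ribosomal protein (0.12) calls in MDAH-2774 were lost. The ribosomal protein call was also lost in OVSAHO (0.22) and for the difference (0.062). The difference reversed for KBTBD11 (-0.14) with log2(RPKM + 1) and for KCNMA1 (0.41 with log2(RPKM + 1), 0.22 with log2(RPKM + 0.1)). Both genes were near 0 counts in OVSAHO, where a pseudocount shrinks the change. The reversed KCNMA1 difference passed with log2(RPKM + 1) (adjusted p = 0.01) and not with log2(RPKM + 0.1) (0.49), and that of KBTBD11 did not pass (0.51).

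The replicate block gave 1873, 1756 and 1758 genes in MDAH-2774, OVSAHO and for the difference, 269 in the same direction in both lines, and 19, 13 and 17 lists. With it the calls were lost for STAT3 in MDAH-2774 (adjusted p = 0.1), fatty acid synthesis genes (0.05) and lestaurtinib-bound kinases (0.056) in MDAH-2774, heat shock (0.052) and ribosomal protein genes (0.1) in OVSAHO, and the kinase list for the difference (0.055). Replicates with the same number did not deviate together (r = -0.059, 0.046 and -0.197 in MDAH-2774, -0.228, 0.094 and -0.004 in OVSAHO), so the numbers do not pair the libraries. Genes with few counts are less certain, among them those that rest on 1 library.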

Other observations

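The test below was chosen only after the result was seen. In OVSAHO, CGA, SST, DUSP1 and the long non-coding LINC00473 rose by 4.64, 2.41, 2.50 and 2.95 on the log2 scale. These genes are known targets of the cyclic AMP responsive factor CREB. LINC00473 had a larger fitted change in MDAH-2774, 7.94 (difference -5, adjusted p of the difference 0.012). Its counts are not given here. LRRN2 and PDE6B, at a fitted 7.02 and 7.04 in MDAH-2774, had no count in vehicle, so a fold of this size may depend on the settings of the fit. BDNF rose more in MDAH-2774 (3.03 against 1.45, difference -1.58, adjusted p of the difference 0.0047). NR4A1, NR4A2 and PDE4D rose in MDAH-2774 too, while FOS fell there by 2.01 (difference 3.2). DUSP1 did not pass there (0.24, difference 2.27), and CGA and SST had no count there.

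A rise of CREB targets as a set in OVSAHO is a hypothesis, tested with a list written after those genes were seen and without them. Of 22 measured members 8 rose and 1 fell, with a median of 0.63. SIK1 rose by 1.35, PER1 by 1.16, CREM by 0.70 and FOS by 1.19. Camera gave p = 0.0024, and 0.026 with an estimated correlation. With RGS2, another gene that had prompted the list and was in its first version, p was 0.00048 and 0.0065, and without members of the AP-1 list 0.024 and 0.048. Over the 9 tests run (3 versions in 3 contrasts), the adjusted p in OVSAHO at the preset correlation was 0.011 for the list, 0.0043 with RGS2 and 0.073 without the AP-1 members, and with an estimated correlation 0.12, 0.058 and 0.14. The first 2 passed at the preset correlation and none with an estimated one, so whether CREB targets may have risen as a set stays open. The list did not pass in MDAH-2774 (camera adjusted p = 0.55) and was not shown to differ between the lines (camera adjusted p = 0.27).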
